A study of Mus musculus with 10 samples.

How the data were processed

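RNA was profiled from 10 individual mouse fetal livers at embryonic day 14.5, 5 from wild type fetuses and 5 from fetuses lacking Zfp36l2, all on a mixed B6 and 129 background. Per the labels' protocols, total RNA was purified on silica columns and 1 µg per liver was turned into biotin-labelled cRNA with a one-cycle Affymetrix kit. The probe annotation names the array as a whole-genome mouse expression array. Genotype and replicate number were taken from the sample titles, and each liver is a separate animal.

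The deposited table holds 1 linear intensity per probe set and array, already background-subtracted, with 45037 probe sets and no control probe sets. The software and scaling by which the authors made these intensities are not given in the sources used here. That the values are linear was read from their range, which runs below 0 and up to 18272. Values at or below 0 made up 21.5% of the table. Array medians ran from 19.5 to 25.01, a ratio of 1.28. Because these medians lay more than 10% apart, a rule set before the data were examined called for quantile normalization, done here on the linear values. Values at or below 0 were then set to the lowest positive normalized value, 0.000978, and log2 was taken. This very low floor turns a dim value into a large negative log2 value, so folds of dim genes on this scale are inflated and their spread is wide.

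Probe sets with a mean log2 value under the 40th percentile were left out, which kept 27022, of which 17.1% had a value at the floor on at least 1 array. Knockout was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, genotype as the only term, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A gene is "called" where its adjusted p passes. Of the probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none in the annotation, and only the first kind entered gene counts. A gene was represented by its probe set with the highest mean log2 value. Standard errors are those of limma, SDs are over 5 livers on the normalized linear scale, and folds are the antilog of the mean log2 difference. For an array the number of livers limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

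The 26 gene lists were fixed before the data were examined. They cover erythroid cells, haem synthesis and iron uptake, globins, megakaryocytes and platelets, stem and progenitor cells, neutrophil lineage, monocytes and macrophages, mast cells with basophils and eosinophils, B-lymphoid cells, T and NK cells, hepatoblasts and hepatocytes, bile duct cells, stellate with mesenchymal and mesothelial cells, endothelial cells, gut and pancreas, muscle and heart, known ZFP36-family target mRNAs, cell cycle, p53 targets, interferon-induced genes, hypoxia and glycolysis, immediate early genes, heat shock and unfolded protein response, cholesterol synthesis, acute phase proteins, and haematopoietic growth factors. Of their 517 symbols 472 had a probe set, and 18 genes stood in 2 lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 26 lists. A liver's list score is the median over the list's genes of its log2 value minus the gene's mean, compared by a two-sided exact permutation test of the 10 livers. That score test was added after the data were seen.

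Gene order on chromosome 17 came from a RefSeq gene table (GRCm38.p6), used for order only. The planned window held 25 tested genes on either side of Zfp36l2. It was compared with other genes by a two-sided Fisher's exact test, and with all windows of as many genes on other chromosomes by mean absolute moderated t. A planned search of 3' untranslated regions for the binding motif of the family was not run, and those sequences were not analysed here.

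The rule for genes named in the text was also fixed before the data were examined. It takes the 3 family members, the 10 largest called rises and 10 largest called falls with no overlap of the genotypes, and up to 4 called members of each list or, where none passed, its member with the highest mean. Members named because they passed over their list alone, and genes named because they were called with a floor of 16, were chosen after values were seen.

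The method was tested on simulated data made from the real probe sets. In 5 simulations the main setting recovered 24% of 1.5-fold, 39.2% of 2-fold, 54% of 3-fold and 64.4% of 4-fold changes, with 5.02% false among calls. With a floor of 16 those shares were 26.8%, 48.8%, 83.6% and 94%, with 5.66% false. In 5 simulations without any change no probe set was called. Noise was drawn independently for each probe set, and the floor was not applied again after the changes were added. Recovery near the floor may therefore be overstated, and variation shared between genes was not simulated. The alternatives covered normalization, floor, offset, filter, variance model, array weights, covariates, threshold, set test and each liver left out in turn. The floors of 16 and 32 were added after the data were seen. Outlying livers were sought with Dixon's ratio.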

Results

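Gene expression was measured on one array for each of 10 mouse fetal livers at embryonic day 14.5, 5 wild type and 5 Zfp36l2 knockout. Zfp36l2 encodes an RNA-binding protein of the tristetraprolin family, which binds AU-rich elements and promotes mRNA decay. At this age the liver is the main site of blood formation. The comparison asks which transcripts differ in the fetal liver without this protein. Array medians lay between 19.5 and 25.01 intensity units before normalization, and between 20.7% and 22.6% of values on each array were at or below 0. The mean correlation of an array with the others ran from 0.967 to 0.972.

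Zfp36l2 fell in the knockout livers. Its brightest probe set averaged 434 ± 91.0 in wild type and 102 ± 11.3 in knockout livers (SD, n = 5), a 4.21-fold difference. The change was -2.08 ± 0.13 on the log2 scale (SE; limma adjusted p = 1.97e-05), and the genotypes did not overlap (exact permutation p = 0.00794, the smallest that 5 against 5 livers can give). Values of 389 to 596 in wild type stood against 82.3 to 109 in knockout livers. A second Zfp36l2 probe set was dim in both genotypes, at 31.4 and 25.05, with an adjusted p of 0.789, and another averaged below 0 in both. Which part of the gene each probe set covers, relative to the targeted part, was not analysed here. Of the paralogs, Zfp36l1 averaged 683 ± 95.0 and 933 ± 87.8, a log2 difference of 0.46 ± 0.10 that missed the threshold (limma adjusted p = 0.0994) although no livers overlapped. Zfp36 averaged 51.6 and 74.0 (adjusted p = 0.378).

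Among called genes, Pf4 and Ppbp, chemokines stored in platelet granules, fell most after Zfp36l2. Pf4 went from 1717 ± 273 to 656 ± 126 (log2 -1.39 ± 0.13, limma adjusted p = 0.000951) and Ppbp from 2146 ± 357 to 825 ± 168 (log2 -1.38 ± 0.14, adjusted p = 0.00137). Plek, a major substrate of protein kinase C in platelets, fell by 0.98 ± 0.12 (adjusted p = 0.0138). The other fallen genes were Yipf4, Emilin2, Cdc42ep3 and Rsu1, with log2 changes of -0.93, -0.89, -0.81 and -0.58. Crot, which encodes a peroxisomal carnitine acyltransferase, was the single called gene that rose, from 566 ± 46.8 to 772 ± 31.2 (log2 0.45 ± 0.07, adjusted p = 0.0286). In all, limma called 9 of 12741 genes, 1 higher and 8 lower, from 11 of 27022 probe sets, and 2276 probe sets had an unadjusted p under 0.05. Crot was called in 14 of 24 settings and Rsu1 in 18; Crot was not called without wild type replicate 2 or 4 or knockout replicate 2, 3, 4 or 5, at log2 changes of 0.42 to 0.46, nor Rsu1 without wild type replicate 3 or 4 or knockout replicate 2 or 4, at -0.55 to -0.59. Counts depended on single livers: 76 genes were called without wild type replicate 5, 6 without wild type replicate 2 or 3, 4 without knockout replicate 2 and 5 without knockout replicate 4.

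**Figure D1:**
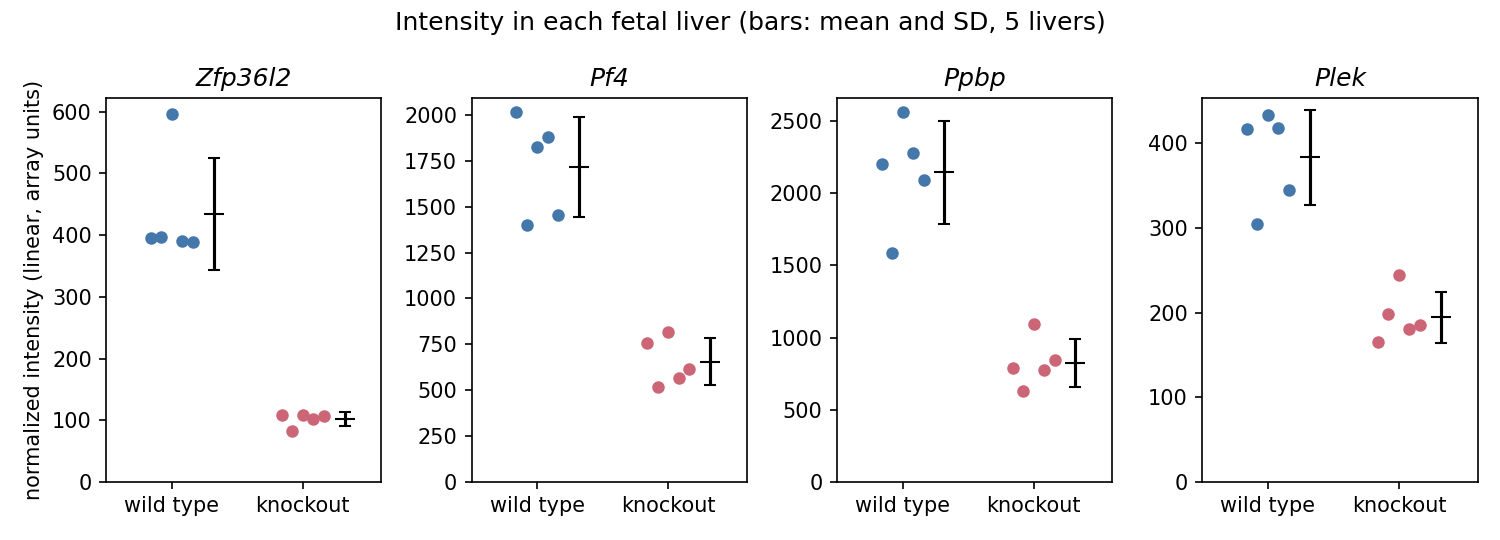
Normalized linear intensity (vertical axes, array units, starting at 0) of Zfp36l2, Pf4, Ppbp and Plek in each wild type and knockout liver, with points for livers and bars for the mean and SD of 5 livers. In all 4 genes every knockout liver lies below every wild type liver, as for Zfp36l2 at 82.3 to 109 against 389 to 596.

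With values under 16 set to 16, a floor chosen after the data were seen, limma called 42 genes, 20 higher and 22 lower, which included all 9 above. Among the added falls were the platelet glycoprotein Gp5 (log2 -1.59, adjusted p = 0.0240), Rgs18 (-1.21), the platelet lipoxygenase Alox12 (-1.11) and Itgb3 (-1.11). Lat averaged 70.0 in wild type and 18.5 in knockout livers, and Fgf13 52.3 and 9.24, near or under that floor, and the eosinophil peroxidase Epx, which rose (adjusted p = 0.0285), averaged 32.2 and 158 with 2 wild type livers under it, so no fold is given for these 3. Among the added rises were the interferon-induced Rsad2 (1.74), Car7 (1.61), Pfkp (1.47), Lgals3 (0.89), Ctsc (0.69), Dnajc12 (0.69), the NF-kappa-B inhibitor Nfkbia (0.69), Ifitm3 (0.67) and Tgfbi (0.67). In the main setting the other tested Nfkbia probe sets changed by 0.39, 0.30 and 0.24 (limma adjusted p = 0.387, 0.737 and 0.735).

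The megakaryocyte and platelet list fell as a group. Of 19 tested members 17 had negative changes, with a median log2 change of -0.84. Pf4, Ppbp and Plek fell over all genes and 15 members fell adjusted over the list alone, among them Gp5, Itga2b, Itgb3 and Vwf. Tubb1 and Selp had positive values that did not pass. The list's score was higher in each wild type liver (0.17 to 0.76) than in any knockout liver (-0.57 to -0.06). Camera gave an adjusted p of 6.56e-21 at the preset correlation and adjusted p = 0.0925 with an estimated correlation, while fry gave 0.00486. The exact permutation p of the scores was 0.00794, the smallest this test can give, and 0.0688 after adjustment over 26 lists. A list alone at that limit cannot pass the adjustment, so the adjusted value does not decide whether the scores differ.

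The erythroid list was lower at the preset correlation, with 20 of 22 members negative and a median of -0.18 (camera adjusted p = 1.50e-10, and adjusted p = 0.216 with an estimated correlation). In limma 0 members fell over all genes, 11 at an unadjusted p under 0.05 and 9 adjusted over the list alone, among them Ank1 (-0.29), Gata1 (-0.21), Icam4 (-0.31) and Rhd (-0.27). Slc4a1, the brightest member, averaged 7929 and 7896. Haem synthesis and iron uptake had a median of -0.12 (adjusted p = 0.000411, and adjusted p = 0.322 with an estimated correlation), with no member passing over the list alone, and -0.07 without wild type replicate 5. The 4 tested globins were not called (adjusted p = 0.609). The cell cycle list was lower, with 28 of 30 members negative, a median of -0.13 (-0.08 without knockout replicate 2) and 5 members falling adjusted over the list alone, such as Plk1 (-0.31), Ccna2 (-0.24) and Mki67 (-0.23). Its camera adjusted p was 2.46e-08, and adjusted p = 0.216 with an estimated correlation.

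Myeloid lists were higher at the preset correlation. In the monocyte and macrophage list 22 of 23 members were positive, with a median of 0.39, and 7 rose adjusted over the list alone, 0 over all genes in limma and 10 at an unadjusted p under 0.05. Lysozyme genes Lyz1 (1.20 ± 0.31) and Lyz2 (1.28 ± 0.32), complement C1qc (0.38) and haem oxygenase Hmox1 (0.50) were among the 7. Camera gave an adjusted p of 2.09e-09 and adjusted p = 0.216 with an estimated correlation, while fry gave 0.0669. The list's score was lower in each wild type liver (-0.51 to 0.12) than in any knockout liver (0.15 to 0.29). Its exact permutation p was 0.00794, again the smallest this test can give, and 0.0688 after adjustment over 26 lists. The neutrophil list had a median of 0.88 (adjusted p = 5.19e-05, and adjusted p = 0.367 with an estimated correlation), with Ltf (1.84), Lcn2 (1.62) and Ngp (1.65) rising adjusted over the list alone. For this list fry gave an adjusted p of 0.271, and the exact permutation p of its scores was 0.111. Its score in wild type replicate 5 (0.92) lay above every knockout liver (-0.08 to 0.78). Mast cell, basophil and eosinophil genes had a median of 0.59 (adjusted p = 0.0349, and adjusted p = 0.226 with an estimated correlation), with Prg2 (0.94) and Epx passing over the list alone. This list was called in 13 of 28 settings, and not without wild type replicate 3 (median 0.27), 4 (0.44) or 5 (0.31) or knockout replicate 3 (0.51) or 5 (0.93); without knockout replicate 2 its median was 1.05. All 11 acute phase genes were positive, with a median of 0.96 and 7 rising adjusted over the list alone, including Lcn2, Itih4 (0.96), Cp (1.19) and Hpx (0.49), at an adjusted p of 4.80e-08 and adjusted p = 0.216 with an estimated correlation. The livers of 1 genotype differed widely here: the acute phase score ran from -1.19 in wild type replicate 4 to 0.44 in wild type replicate 5, and the neutrophil score from -1.53 to 0.92 in the same 2 livers. Without wild type replicate 4 the medians were 0.45 for acute phase and 0.47 for neutrophil genes, and with a floor of 16 the acute phase median was 0.59.

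Hypoxia and glycolysis genes were higher, with 19 of 23 positive, a median of 0.23 and 9 rising adjusted over the list alone, among them Ldha (0.27), Ero1a (0.54), Pgk1 (0.46) and Aldoa (0.50). Camera gave an adjusted p of 9.78e-07 and adjusted p = 0.216 with an estimated correlation. Cholesterol synthesis had 16 of 17 members positive and a median of 0.21, with Sqle (0.39) passing over the list alone (adjusted p = 2.15e-06, and adjusted p = 0.216 with an estimated correlation). Interferon-induced genes had a median of 0.35, or 0.17 with a floor of 16, with Rsad2 passing over the list alone (adjusted p = 0.0130, and adjusted p = 0.216 with an estimated correlation). They were not called without wild type replicate 4 (median 0.18), and their median was 0.20 without knockout replicate 2, 0.64 without knockout replicate 5, and 0.58 and 0.65 without wild type replicates 3 and 5. Hepatocyte genes had a median of 0.09 (adjusted p = 0.00525, and adjusted p = 0.385 with an estimated correlation), and Afp averaged 16358 and 16287. That Afp probe set lay near the highest values of the arrays (15719 to 18272 before normalization). Quantile normalization leaves little room for a difference there. Hepatocyte genes were not called without wild type replicate 3 (0.06) or knockout replicate 5 (0.07), and their median was 0.14 without wild type replicate 5 and 0.15 without knockout replicate 2. Bile duct genes had a median of 0.16, with Cdh1 (0.33) passing over the list alone (adjusted p = 0.0251, and adjusted p = 0.226 with an estimated correlation), and were not called with a floor of 16 or without wild type replicate 2 (0.15) or 4 (0.15) or knockout replicate 5 (0.20). Their median was 0.29 without knockout replicate 1 and 0.40 without knockout replicate 3. In all, camera called 13 of 26 lists at the preset correlation, 9 higher and 4 lower, 14 with a floor of 16, and 0 with an estimated correlation. Fry called 2, and 12 had an unadjusted exact permutation p of their liver scores under 0.05 with 0 after adjustment. These 12 were not all among the 13, as stem and progenitor cells, muscle and heart and known ZFP36-family targets were included. Called lists that missed 0.05 in the score test were haem synthesis and iron uptake (exact permutation p = 0.0873) and the neutrophil lineage (0.111). Hepatocytes (0.254) and cholesterol synthesis (0.0714) missed it too. Even the smallest p of that score test cannot pass the adjustment for a list alone.

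Camera did not call the remaining lists at the preset correlation in the main setting. Known mRNA targets of the ZFP36 family had a median of 0.05 (adjusted p = 0.0777, and 0.0446 with a floor of 16, where they were called, but 0.184 with that floor and an estimated correlation), with Cxcl1 (1.37 ± 0.28) and Birc3 (0.65 ± 0.18) passing over the list alone and Mcl1 at 0.03. Stem and progenitor genes had a median of 0.02 and a mean of -0.14, which differ in sign (camera adjusted p = 0.137), and were 1 of the 2 lists called by fry (adjusted p = 0.0398), with Slamf1 (-1.27) and Lmo2 (-0.19) passing over the list alone. Adjusted p-values were 0.0852 for B-lymphoid genes and for heat shock and the unfolded protein response, where Xbp1 (0.30), Hsp90b1 (0.21) and Ddit3 (-0.52) passed over the list alone and camera called the list with a floor of 16 (adjusted p = 0.0251, and adjusted p = 0.295 with that floor and an estimated correlation). They were 0.918 for T and NK cells, whose median of -0.85 and mean of 0.48 differ in sign, 0.583 for stellate cells, 0.137 for endothelial cells, 0.583 for gut and pancreas, 0.633 for muscle and heart, 0.918 for p53 targets, 0.211 for immediate early genes and 0.885 for growth factors, where Igf2 (0.25) passed over the list alone.

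**Figure D2:**
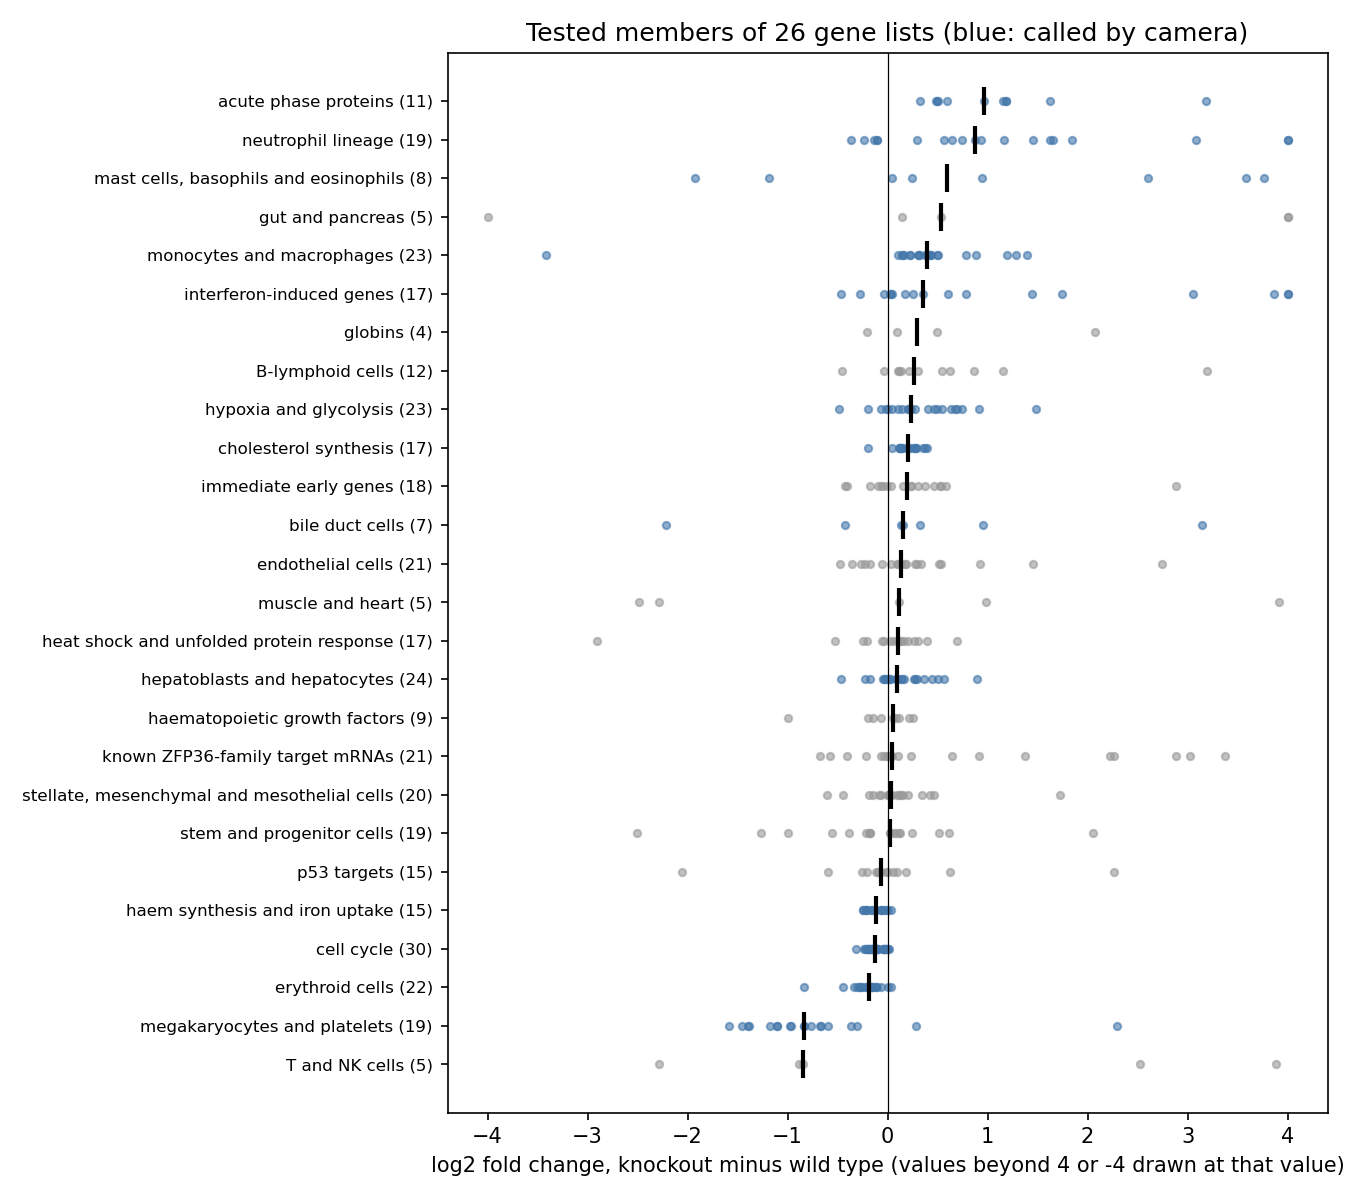
Log2 fold change of each tested list member (horizontal axis, knockout minus wild type, values beyond 4 or -4 drawn at that value), by list with the number tested in brackets. Points are genes, black ticks are list medians and blue marks lists called at the preset correlation, from the megakaryocyte list at -0.84 to acute phase proteins at 0.96.

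Of the 8 called genes other than Zfp36l2, Yipf4, Emilin2 and Cdc42ep3 lie on chromosome 17, the chromosome of Zfp36l2, at 30, 47 and 15 tested genes from it, and all 3 fell. Two-sided Fisher's exact test gave p = 0.00526 for 3 of 615 genes on that chromosome against 5 of 12095 elsewhere, and with a floor of 16 p = 0.126 among genes tested in both settings and p = 0.0465 among all genes tested with that floor. In the planned window of 25 genes on either side, 1 of 50 was called against 7 others (Fisher's exact p = 0.0310). The window's mean absolute t was 1.31, against a median of 1.07 in windows elsewhere, of which 4.68% were as large. A wider window of up to 50 genes on either side, which reached the end of the tested genes on one side and held 79, was chosen after the places of the called genes were seen. It held the 3 called genes (Fisher's exact p = 1.27e-05). With a floor of 16 it held 3 called genes against 37 others among genes tested in both settings (Fisher's exact p = 0.00194). Drawn over all genes tested with that floor, the wider window held 77 genes, of which 4 were called, against 37 others (Fisher's exact p = 0.000104). The call gained there, and on the whole chromosome, was of a dim gene averaging 61.1 in wild type and -4.46 in knockout livers. With 3 knockout livers under that floor, the p-values that count this gene rest partly on values set to the floor. Both Cdc42ep3 probe sets fell in every knockout liver, from 394 to 226 and from 224 to 152. Of 24 settings, Emilin2 was called in 7, Cdc42ep3 in 14 and Yipf4 in 18. Left out singly, knockout replicate 2 or 4 ended the call of Yipf4 (-0.92 without either), wild type replicate 1, 2 or 3 or knockout replicate 1, 2 or 4 that of Cdc42ep3 (-0.82 to -0.73), and any liver but wild type replicate 5 that of Emilin2 (-0.94 to -0.79).

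**Figure D3:**
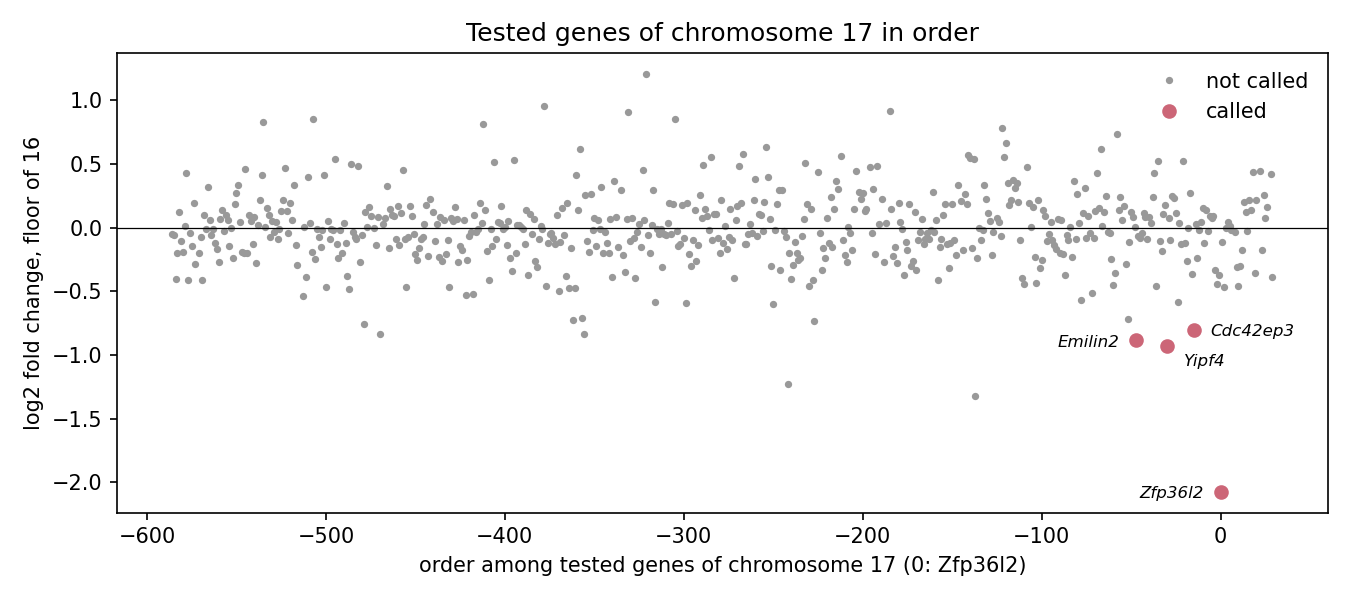
Log2 fold change with a floor of 16 (vertical axis) of chromosome 17 genes tested in both settings by order from Zfp36l2 at 0 (horizontal axis). Red points are genes called without that floor; Cdc42ep3, Yipf4 and Emilin2 lie at -0.81, -0.93 and -0.89.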

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

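Every test of an explanation in this part was worded after its result, or values it rests on, had been seen, and for the erythroid share 1 rule was made stricter and 1 test added after the results were known; only the window on chromosome 17 and the comparison with the Y-linked level as a covariate had been planned.

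Dixon's ratio put 17 values apart from the other livers of their genotype among 206 groups tested, where chance gives about 1 in 20 groups, or 10.3. Zfp36l2 stood apart in wild type replicate 3 (log2 9.22, nearest 8.63) and knockout replicate 2 (6.36, nearest 6.68). Hbb-y was low in wild type replicate 5 (11.8, others from 13.6). Lyz1 (10.8) and Lyz2 (10.5) were low in knockout replicate 2. In knockout replicate 1 the log2 values of Zap70 (0.19), Fgf13 (-9.998, the floor) and Alox12 (5.31) were low, and in knockout replicate 3 that of Lat (-9.998, the floor). Lyve1 was low (8.15) and Dnajc12 high (9.30) in knockout replicate 5, Ddit3 was low (6.22) in knockout replicate 4, Plk1 was low (9.49) in wild type replicate 2 and Tgfbi was high (7.66) in wild type replicate 5. The megakaryocyte score of knockout replicate 3 (-0.0644) lay above the other knockout livers, the endothelial score of wild type replicate 1 (0.0869) above and its cell cycle score (-0.0304) below the other wild type livers.

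The real grouping called 11 probe sets, and 2 of 100 splits of the 10 livers into 5 and 5, the real one included, reached as many, with 13 as the highest other value. With a floor of 16 it called 57, and again 2 of 100 splits reached as many, the highest other being 70. Under 5% of the splits reached either count. Because another split exceeded both, counts of this size also arose under a grouping other than genotype, and chance is not excluded. The other split in both cases exchanges wild type replicate 5 with knockout replicate 2, and its called probe sets in the main setting, 13 in all, belong to Itgb2, Cp, Plac8, Ly6e, Cd52, Ptprc, Cytip, Kng1, Lyz1, Lyz2 and Ifitm6. For the 13 lists called, 1 of 100 splits, the real one, reached that number, with 12 as the highest other, so random splits also call many lists at the preset correlation.

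The megakaryocyte and platelet list fell with a median of -0.84. Only the real split among 100 gave an absolute mean t as large as 4.35, the highest other being 3.17. Whether megakaryocytes were fewer or held less of these transcripts was not tested.

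The fallen genes on chromosome 17 may reflect B6 or 129 DNA linked to the targeted allele. Of windows elsewhere 4.68% had as large a mean absolute t as the planned window, just under 5%, so this explanation stays open. Fewer megakaryocyte transcripts cannot be told apart from it. With each liver's megakaryocyte score as a covariate the median change of the 3 genes was -0.70. The log2 change was -0.60 ± 0.31 (SE) for Cdc42ep3, -0.70 ± 0.36 for Emilin2 and -1.16 ± 0.33 for Yipf4. Because the score itself separates the genotypes, this fit cannot exclude fewer megakaryocyte transcripts for any of the 3 genes, Yipf4 included. An effect of the targeted allele on its neighbours was not tested.

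The macrophage list, called higher at the preset correlation only, had a median of 0.39, and 0.38 with the Y-linked level as a covariate, which argues against the sex of the fetuses. Exchanged labels of wild type replicate 5 and knockout replicate 2 are argued against by Zfp36l2 itself, 4.72 times as bright in the former. A lower share of erythroid cells would raise all other types alike, but the megakaryocyte score shifted by -0.92. Its gap to the macrophage score shifted by 1.34 ± 0.21 (SE, exact permutation p = 0.00794, adjusted over 4 types 0.0317). This argues against that share as the only difference between the genotypes. Most of that gap was the megakaryocyte fall, so it does not show why the macrophage list rose. The gaps of the macrophage score to the hepatocyte, stellate and endothelial scores shifted by 0.30, 0.37 and 0.30 (exact permutation p adjusted over 4 types 0.0635 for each). A lower erythroid share as the source of the macrophage rise, beside a separate megakaryocyte fall, cannot be told apart. The macrophage score shifted by 0.32 beyond the mean of the hepatocyte, stellate and endothelial scores, with an exact permutation p of 0.0238 that became 0.0714 adjusted over 3 lists. A change in the myeloid cells or their share may also be present, which these arrays leave open.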

How the results depend on the processing

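Zfp36l2 passed in all 24 settings (log2 -2.11 to -1.96). Pf4, Ppbp and Plek lost their calls without the variance trend and in the plain pooled-variance test. Plek, by its brightest probe set, also lost its call at an adjusted p under 0.01. Another Plek probe set passed that threshold in the main setting, going from 316 to 148 (log2 -1.09, limma adjusted p = 0.000951). The remaining Plek probe set went from 114 to 68.2 and was not called (limma adjusted p = 0.271). Over settings other than leaving out a liver, 983 of 1074 gene values and 378 of 467 list values kept direction and side of the threshold. The floors of 16 and 32, the score permutation and the wider window were chosen after seeing the data, and the comparison of the whole chromosome was not planned. The robust fit was not applied to lists, and the motif test was not run. Dim signal limits what can be read: 17.1% of tested probe sets had a value at the floor. Except where fewer livers, another filter or a stricter threshold is the setting, the cause was not tested.

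Genes called moved from 9 to 25 at the 60th percentile filter, 1 without trend, 15 robust, 16 with array weights, 3 at an adjusted p under 0.01, 1 in the plain test, 42 with a floor of 16, and 4 to 76 leaving out 1 liver (76 without wild type replicate 5, 4 without knockout replicate 2). Probe sets called moved from 11 to 30 unfiltered, 29 at the 60th percentile, 2 without trend, 17 robust, 20 with array weights, 4 at 0.01, 1 in the plain test, 57 with a floor of 16, and 5 to 102 leaving out 1 liver. The called gene in the planned window went from 1 to 0 unfiltered, without trend, at 0.01, in the plain test and with a floor of 32, to 2 where the window was drawn over all genes tested with a floor of 16 (Fisher's exact p = 0.0111), and ranged from 0 to 1 leaving out 1 liver.

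A fit with the replicate block called 21 genes and 28 probe sets. Deviations of same-numbered livers correlated at 0.001 to 0.031 (0.028 to 0.130 with a floor of 16). With that floor their mean was 0.075, against -0.019 between livers of other numbers. These correlations were low, so the numbers were not taken to pair livers, but a factor shared by number is not ruled out. As a hint, with that floor wild type replicates 3, 4 and 5 correlated best with their own number and 1 and 2 did not.

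Lists called moved from 13 to 14 with a floor of 16, 0 with an estimated correlation, 2 with fry, 0 with a floor of 16 and an estimated correlation, and 0 by exact permutation of scores. The megakaryocyte median stayed at -0.836, -0.835 and -0.836 with an estimated correlation, with that and a floor of 16, and by score permutation, but missed the threshold. For score permutation the miss decides little, because the unadjusted p of this list was already the smallest that test can give. Medians of called lists that moved over 1.5 times were, with a floor of 32, 0.30 for the neutrophil lineage, 0.37 for mast cells, basophils and eosinophils, 0.12 for interferon-induced genes and 0.53 for acute phase proteins. The mast cell list moved to 0.94 at the 60th percentile and was lost unfiltered (0.05), and with a median shift, the replicate block, the Y-linked level, the mean of probe sets and no trend, and the interferon list at the 60th percentile (0.04). Hypoxia and glycolysis moved to 0.40 by the mean of probe sets. The bile duct list was also lost unfiltered (0.15), with the 25th percentile added (0.15) and without probe sets marked for possible cross-hybridisation (0.14).

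All sign changes were in results not called by limma or camera in the main setting, although fry called the stem and progenitor list. As deposited the values were -0.0141 for stem and progenitor cells, 1.34 for T and NK cells, -0.0683 for Slc4a1, -0.0395 for Slc25a37, -0.0102 for Col3a1 and -0.0307 for Hspa8. With arrays shifted to one median the values were 1.36 for T and NK cells, -0.0433 for Slc4a1, -0.0144 for Slc25a37, 0.00121 for Ei24 and -0.00564 for Hspa8. With the 25th percentile (2.495) added the values were 0.0292 for T and NK cells and -0.360 for muscle and heart. With the Y-linked level as a covariate the values were -0.0295 for stem and progenitor cells, -0.0155 for Slc4a1 and 0.000214 for Afp. Without probe sets marked for possible cross-hybridisation the values were -0.0910 for stem and progenitor cells, -1.09 for muscle and heart and -0.00737 for haematopoietic growth factors. By the mean of a gene's probe sets the values were -0.0388 for stem and progenitor cells, 1.11 for T and NK cells and -0.186 for haematopoietic growth factors. With a floor of 16 the values were -0.157 for globins and -0.0793 for stem and progenitor cells. With a floor of 32 the values were -0.137 for globins, -0.0451 for stem and progenitor cells, -0.00530 for gut and pancreas and 0.0752 for Zap70. With that floor of 16 and an estimated correlation the values were -0.157 for globins and -0.0793 for stem and progenitor cells.

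Leaving out 1 liver gave -0.187 to 0.0352 for stem and progenitor cells, -1.67 to 0.494 for muscle and heart, -0.0822 to 0.0551 for Slc4a1, -0.0121 to 0.0739 for Slc25a37, -0.0160 to 0.0825 for Mcl1, -0.0754 to 0.120 for stellate, mesenchymal and mesothelial cells, -0.111 to 0.126 for Col3a1, -1.05 to 2.40 for T and NK cells, -0.199 to 0.391 for Tff3. It gave -0.0573 to 0.370 for Myl2, -0.0387 to 0.520 for globins, -0.270 to 0.284 for Hbb-y, -0.0130 to 0.0784 for Hspa8, -1.29 to 0.273 for Zap70, -0.0785 to 0.0254 for p53 targets, -0.0669 to 0.135 for haematopoietic growth factors, -0.0125 to 0.00641 for Afp, -0.0346 to 3.07 for gut and pancreas and -0.0449 to 0.0219 for Ei24.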

Other observations

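Of the 3 Yipf4 probe sets, the brightest went from 439 to 228 and another from 108 to 37.7, while the remaining one was dim at 21.8 and 6.84 (exact permutation p = 0.444).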
